A study of Mus musculus with 8 samples.

How the data were processed

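Expression was measured in total RNA from lineage-negative bone marrow cells, the fraction depleted of cells carrying markers of mature blood lineages, after 24 h in culture. Per the labels, RNA was purified on silica columns, labelled with biotin and hybridised to 8 whole-transcript Affymetrix mouse gene arrays. All cells came from mice that express oncogenic Kras, and the 8 arrays fall into 4 groups of 2 arrays each. A knockout cohort holds a group wild type for Kdm2b and a Kdm2b knockout group, and an overexpression cohort holds its own wild type and a Kdm2b overexpression group. The cohorts were read from the source names and title prefixes in the labels. Each group carries 1 title code, and nothing in the labels says that its 2 arrays came from separate animals or cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Those of gene lists set genes against other genes and do not measure a spread between animals either.

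The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made by robust multi-array average (RMA), which subtracts background, quantile-normalizes and summarises probes, in Affymetrix Expression Console 1.3. The annotation and genome build behind the probe sets are not given in the sources used here. The table holds 269751 probe sets, most of them covering a part of a gene, with values from 2.41 to 14.3. Array medians over probe sets lay between 6.66 and 6.67 in the knockout cohort and between 6.53 and 6.56 in the overexpression cohort.

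Whether the arrays had been normalized together was checked from values repeated on at least 10 probe sets of an array. Between 29.6% and 51.1% of such values were shared by arrays of the same cohort, against at most 0.837% between cohorts, so the cohorts were treated as normalized separately. A test of the overexpression cohort's wild type against the knockout cohort's wild type had been planned and was not run for this reason. All tests compare arrays within a cohort, or compare within-cohort differences. Across probe sets, arrays correlated at 0.977 to 0.984 within a group, 0.972 to 0.980 between the groups of a cohort and 0.949 to 0.962 between cohorts. The number of arrays limits the precision of every value.

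Probe sets were named through the platform's annotation table. It gave 1 gene symbol to 233753 probe sets and several to 5139, and 30859 probe sets were unnamed in the table used. Probe sets with several symbols named no gene. The symbol of 21308 probe sets was updated through the NCBI gene table of assembly GRCm38.p6, which was used for names and for gene order only. This left 23102 genes, of which 23072 were in the NCBI table. No probe set with a single symbol carried Kras, which the naming rule included, so Kras is not analysed here. The value of a gene was the mean over its probe sets (median 10 per tested gene). Members of near-identical families, such as Stfa and Csta, Gbp, H2-Q, Ifi and Ms4a genes, can share probe signal, and their separate values are uncertain.

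Genes in the lowest 30% of mean expression were left out, which kept 16171 genes with a mean of at least 5.07 on the log2 scale. Group means of all 8 arrays were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend and without robust weights, leaving 4 residual degrees of freedom and adding 4.08 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The contrasts were knockout minus its wild type, overexpression minus its wild type, and the difference between these changes. The first pair of contrasts shares no arrays but shares the estimate of each gene's spread. A plus or minus value is a mean with its SD over 2 arrays, and a fold change carries its standard error (SE) from the fit.

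Gene lists for 37 pathways, complexes and cell types were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes. Each list was tested with camera of limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 37 lists. The same test with a correlation estimated from the residuals was an alternative, as was fry, which tests whether a list's genes moved on balance, or in its mixed form in either direction, without setting them against other genes. With the estimated correlation some lists missed the threshold although their estimate was below 0.01. Examples were B lymphoid genes in the knockout (-0.0283) and heme and iron genes with overexpression (-0.0432). Such a miss therefore cannot be put down to correlation between genes alone. The list test of the difference between the comparisons was added after the data were examined. Counts of list members are over all genes tested and, beside these, adjusted over the list alone.

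The rule named Kdm2b and Kras, then the 8 largest changes per direction among genes past the threshold whose groups did not overlap in any array. From each list past its test it took up to 3 members with the largest changes. For the difference between the comparisons it took the 4 largest per direction. Predicted genes and immune receptor segments were counted but not named. Other genes named below illustrate a list's counts or belong to a pattern, and were chosen after their values were seen.

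The fit was tested on simulated data with the real genes' means and spread. For the knockout comparison over 16171 genes it recovered 94% of 50 genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 1.5 or 2, with 9 false calls among 206. The test of the difference between the comparisons recovered 40% of those changed by 0.5 and 100% of the larger changes. The simulated overexpression comparison, which held no change, gave 0 calls. Alternatives covered the filter on dim genes, the summary of a gene's probe sets, array centring, quantile normalization, the variance model, the arrays in the fit, the replicate number as a block, each array left out in turn, probe sets tested singly and the list test. With 2 arrays per group neither a test for outlying arrays nor a count of other splits was made.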

Results

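Expression was profiled on 8 arrays to ask how the loss or gain of KDM2B changes lineage-negative bone marrow cells of mice with oncogenic Kras. KDM2B is a histone demethylase that also brings a Polycomb complex to unmethylated CpG islands. The knockout and its wild type made up 2 arrays each, as did the overexpressing cells and their own wild type. Of 16171 genes tested, 1861 (11.5%) changed in the knockout and 2102 (13%) changed with overexpression in limma. The SD of the difference between the 2 arrays of a group, over genes, was 0.147 in the knockout cohort's wild type, 0.148 in the knockout, 0.140 in the overexpression cohort's wild type and 0.165 with overexpression.

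Kdm2b itself followed the labels in each cohort. Its mean was 6.32 ± 0.10 (SD, n = 2) in the knockout against 7.39 ± 0.14 in wild type, a fall of 2.10-fold (log2 fold change -1.07, SE 0.097, limma adjusted p = 0.000506). With overexpression it was 8.17 ± 0.058 against 6.98 ± 0.14, 2.27-fold higher (1.18, SE 0.097, limma adjusted p = 0.000449). The difference between these changes was -2.26 (SE 0.14, limma adjusted p = 9.93e-05). The gene value averages 22 probe sets that behaved unequally. Of the 17 bright enough to be tested singly, 2 were lower in the knockout past the threshold, with log2 changes of -3.37 and -2.72, and 8 were higher with overexpression, the largest by 4.30. None moved past the threshold the opposite way. A few bright probe sets, with log2 changes of -0.13, -0.49, -0.16 and -0.14, did not rise in the overexpressing cells. Which parts of the gene the deleted allele or the transgene covers is not known from the labels, so a probe set outside them checks nothing.

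**Figure D1:**
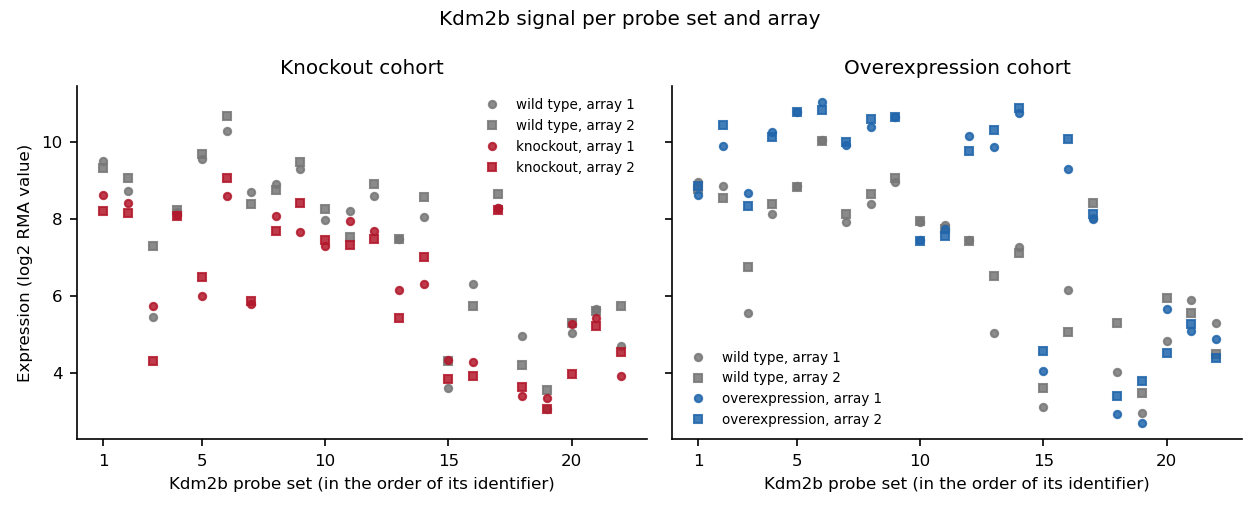
Expression of each of the 22 Kdm2b probe sets (log2 RMA value) on every array of the knockout cohort and of the overexpression cohort, where circles and squares are the 2 arrays of a group. Signal was lower in the knockout on 21 of the 22 probe sets (median -0.99), with the largest falls of -3.37 and -2.72, and overexpression raised some probe sets by up to 4.30 and left others near the wild-type level.

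The knockout comparison asked what changes when Kdm2b is lost. By camera, mitosis genes rose, and interferon-stimulated genes and genes of mast cells and basophils fell. These 3 lists also passed with a correlation estimated from the data, which lists of neutrophil granules, S phase and histones did not. The largest rises were in Stfa2l1, a stefin-like protease inhibitor (9.13-fold, log2 fold change 3.19, SE 0.081), and in the neutrophil granule genes Ngp (7.28-fold, 2.86, SE 0.094) and Ltf, which encodes lactoferrin (5.75-fold, 2.52, SE 0.070). The largest falls were in the class I major histocompatibility gene H2-Q6 (7.24-fold, -2.86, SE 0.13) and in Ly6g, a surface marker of mature neutrophils (6.76-fold, -2.76, SE 0.10). Ly6g is measured by 2 probe sets with changes of -4.29 and -1.22, the latter on the brighter of them. In limma the adjusted p of these genes ran from 1.4e-06 for Stfa2l1 to 1.75e-05 for H2-Q6.

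Of the 1861 genes that changed, 989 rose and 872 fell, and 102 of them changed at least 2-fold (56 up, 46 down). At an unadjusted p under 0.05 there were 4101. The other leading rises were S100a9, a subunit of the neutrophil protein calprotectin (2.42), the stefin family genes Cstdc4 (2.31), Csta3 (2.10) and Stfa1 (1.93), and Srr, which encodes serine racemase (1.94). In wild type the means of Cstdc4 (3.90) and Csta3 (4.72) lay below 5.07, the lowest overall mean kept, so the sizes of their rises are uncertain. The other leading falls were Tjp1, a tight junction scaffold (-2.42), the interferon-inducible GTPases Gbp6 (-2.16) and Iigp1 (-1.85), Fcer1a, the IgE receptor chain of mast cells and basophils (-2.14), the steroid reductase Akr1c18 (-1.86) and the mast cell tryptase Tpsab1 (-1.63). All of them passed the limma threshold, with Gbp6 the weakest at an adjusted p of 0.00305 from a single probe set. Srr rested on its dimmer probe sets, since on its brightest probe set its change was -0.27.

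Of the 37 gene lists, 15 passed camera in the knockout, 8 higher and 7 lower, and 3 of these passed with an estimated correlation. With the preset correlation the mitosis list had the smallest p. Of its 59 tested genes 50 rose and 0 fell (57 and 0 adjusted over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 3.56e-34, adjusted p = 0.0414 with an estimated correlation). The kinesin Kif15 (0.81, SE 0.084), the anaphase activator Cdc20 (0.79, SE 0.067) and the kinetochore gene Ndc80 (0.77, SE 0.087) led it. On their brightest probe sets Kif15 (0.31, limma adjusted p = 0.505) and Cdc20 (0.63, limma adjusted p = 0.0717) did not pass. Of 48 genes of DNA replication and S phase 20 rose and 0 fell (28 and 0 adjusted over the list alone), among them the primase Prim1 (0.63), thymidylate synthase Tyms (0.56) and E2f8 (0.55), with a median of 0.21 (camera adjusted p = 1.23e-12, adjusted p = 0.116 with an estimated correlation). Replication-dependent histones had 9 of 17 genes higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 2.59e-07, adjusted p = 0.0709 with an estimated correlation). H1f1 (1.01), H2bc12 (0.68) and H2bc3 (0.64) led them.

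Interferon-stimulated genes fell as a group. Of 62 tested genes 45 fell and 2 rose (56 and 2 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 1.13e-27, adjusted p = 0.00638 with an estimated correlation). After Gbp6 and Iigp1 the largest fall was in the oligoadenylate synthetase gene Oas1g (-1.29, SE 0.10). The exceptions that rose were Ifi44 (0.59) and Xaf1 (0.56). Of 23 mast cell and basophil genes 14 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 5.28e-10, adjusted p = 0.0414 with an estimated correlation). Beside Fcer1a and Tpsab1 they included Gzmb, a granzyme (-1.49, SE 0.064), and the chymase Cma1 (-1.08), while the basophil protease Prss34 rose (0.67).

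Markers of other blood cell types moved too, although the cells had been depleted of mature lineages before culture. Primary granule genes of early neutrophils had 9 of 15 members higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 4.15e-07, adjusted p = 0.116 with an estimated correlation). Myeloperoxidase Mpo (1.63, SE 0.087), the elastase Elane (1.04, SE 0.069) and the transcription factor Gfi1 (0.71, SE 0.10) led them. Secondary granule and mature neutrophil genes split. Of 27 tested 13 rose and 5 fell (15 and 6 adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.358 with an estimated correlation). Granule genes such as Ngp and Ltf rose, and Ly6g, the protease genes Mmp9 (-0.81) and Mmp25 (-0.78) and the formyl peptide receptors Fpr1 (-0.62) and Fpr2 (-0.70) fell. Of 35 monocyte and macrophage genes 12 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 3.81e-05, adjusted p = 0.213 with an estimated correlation). These included the transglutaminase gene F13a1 (-1.43) and complement C1qa (-0.88) on the lower side and the chemokine receptor Cx3cr1 (1.12) on the higher side.

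Of 26 B lymphoid genes 9 fell and 0 rose (12 and 1 adjusted over the list alone, camera adjusted p = 6.05e-06, adjusted p = 0.0523 with an estimated correlation). On the brightest probe set of each gene their median was -0.02 and the list did not pass (camera adjusted p = 0.351). They were led by the receptor chain Cd79a (-1.09), the terminal transferase Dntt (-1.07) and Ms4a1, which encodes CD20 (-0.74). Of 14 natural killer and cytotoxic genes 6 fell and 2 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.00438, adjusted p = 0.116 with an estimated correlation), with Gzmb, Ccl5 (-1.18) and Gzmc (-1.16) the largest.

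Growth, metabolic and KDM2B partner lists passed camera as well. Of 55 genes of ribosome biogenesis and MYC 8 rose and 0 fell (11 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 4.15e-07, adjusted p = 0.187 with an estimated correlation), among them Myc (0.39), Npm3 (0.37) and Dkc1 (0.35). Cholesterol synthesis had 4 of 19 genes higher, led by Insig1 (0.52), Fdps (0.38) and Cyp51 (0.36), and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.449 with an estimated correlation). It missed the threshold without replicate 1 of the wild type (median 0.098) or of the knockout (median 0.113). With the median of a gene's probe sets it did not pass either (median 0.089, camera adjusted p = 0.11). Nor did it in fry for genes moving on balance (adjusted p = 0.0564). Glycolysis and hypoxia genes had 6 of 35 lower and 1 higher (7 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.00199, adjusted p = 0.116 with an estimated correlation). The falls included the collagen prolyl hydroxylases P4ha2 (-0.56) and P4ha1 (-0.49) and the peptide hormone Adm (-0.46). Of the 9 partners of KDM2B in its Polycomb complex, Bcor rose (0.49, SE 0.061, limma adjusted p = 0.00196), and it was also the only member to pass over the list alone. The values of Bcorl1 (0.23, limma adjusted p = 0.0862) and Pcgf1 (0.19, limma adjusted p = 0.376) did not pass. The list lay at the threshold (camera adjusted p = 0.0491, adjusted p = 0.399 with an estimated correlation) and missed it when any array of the knockout cohort was left out, with camera adjusted p from 0.0583 to 0.0983.

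Of the sex-linked list 3 genes could be tested, all Y-linked, and all 3 fell in the knockout, as they did adjusted over the list alone (camera adjusted p = 0.00027, adjusted p = 0.213 with an estimated correlation). The log2 fold changes were -0.89 for Uty (SE 0.10), -0.70 for Eif2s3y (SE 0.12) and -0.68 for Kdm5d (SE 0.087). Their homologs on the X chromosome had values of -0.12 for Kdm6a, 0.03 for Eif2s3x and 0.07 for Kdm5c, none of which passed in limma.

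Lists that did not pass camera in the knockout had medians from -0.30 to 0.17 and adjusted p of 0.0677 or higher. They were CDK inhibitors, COMPASS and Trithorax subunits, cytokine receptors, dendritic cells and MHC class II, eosinophils, erythroid genes, heme and iron handling, histone demethylases other than Kdm2b, the Hoxa cluster, immediate-early and stress genes, inflammation and NF-kB, megakaryocytes, the Notch pathway, other Polycomb subunits, oxidative phosphorylation, p53 targets, RAS-ERK output, ribosomal proteins, stem and progenitor genes, stroma, T lymphoid genes and the unfolded protein response. Among them CDK inhibitors, COMPASS subunits and p53 targets had medians within 0.01 of 0 with a camera direction of the opposite sign.

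The count of changed genes depended on single arrays and on how probe sets were combined. It was 840 to 929 when an array of the knockout cohort was left out (846 and 840 without either wild-type array, 847 and 929 without either knockout array), and 545 with the median of a gene's probe sets. Leaving out at least 1 array also ended the limma calls of 8 named genes, which were Adm, Cyp51, Dkc1, Eif2s3y, Fdps, H2bc3, Ms4a1 and Npm3, with adjusted p from 0.0515 to 0.155. For Adm and Cyp51 any array of the cohort did so. With the median or the brightest of a gene's probe sets, the calls of Cd79a, Cdc20, Cyp51, Dkc1, E2f8, Eif2s3y, Fdps, Gfi1, Gzmc, H1f1, Kdm5d, Kif15, Myc, Npm3, P4ha1, Prim1, Srr and Tyms ended.

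**Figure D2:**
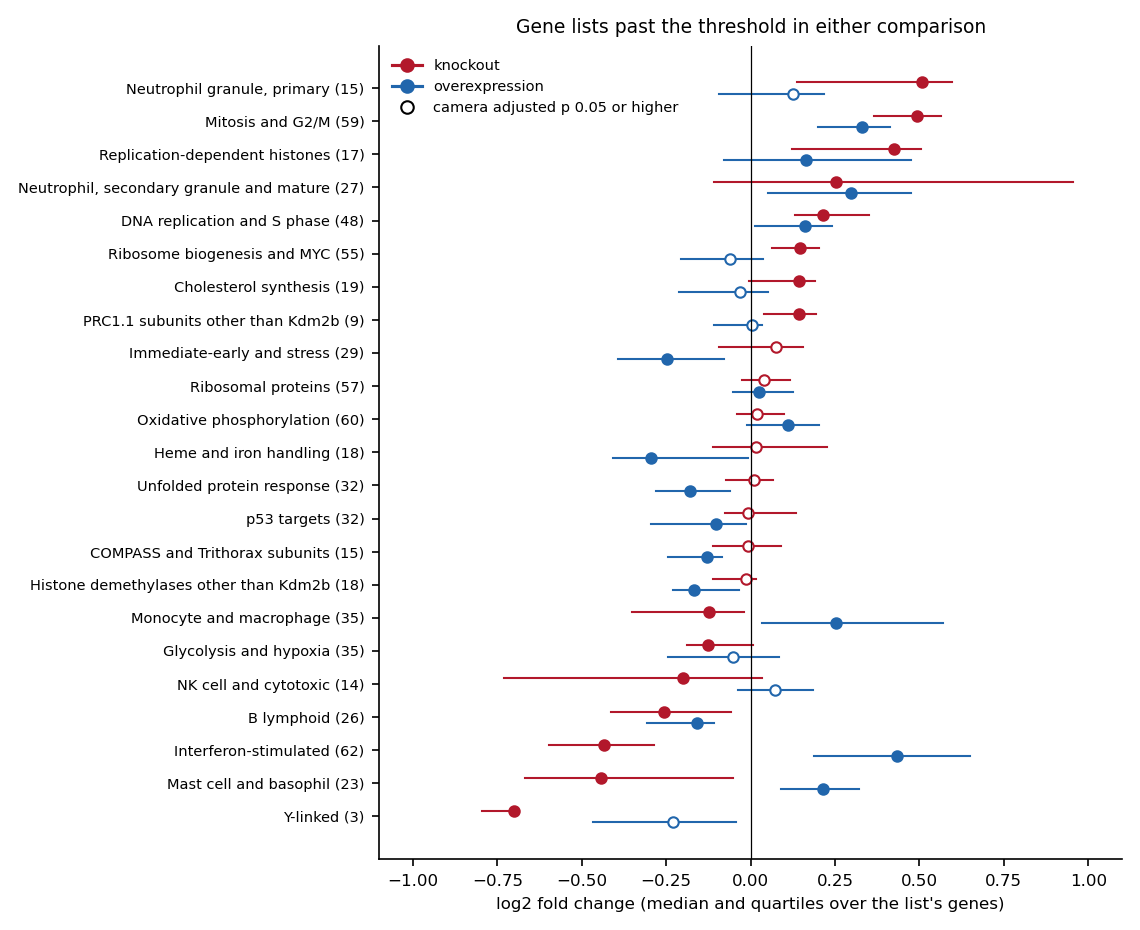
Median (circle) and quartiles (line) of the log2 fold change over the genes of each list that passed camera in at least 1 comparison, with the number of tested genes in parentheses; open circles did not pass. Interferon-stimulated genes lay at a median of -0.43 in the knockout and 0.43 with overexpression, and mitosis genes at 0.49 and 0.33.

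The overexpression comparison asked what changes when Kdm2b is raised. By camera, interferon-stimulated genes rose, which was the only list result that also passed with an estimated correlation. With the preset correlation alone, lists of monocytes and macrophages, secondary granules and mitosis rose, and immediate-early, stress response and iron handling lists fell. The largest rises were in Ctse, the aspartic protease cathepsin E (4.37-fold, log2 fold change 2.13, SE 0.084), Ms4a6b, a membrane protein of immune cells (3.93-fold, 1.97, SE 0.078), and the interferon-inducible Ifi204 (3.85-fold, 1.95, SE 0.12). The largest falls were in Ccn3, a secreted matricellular protein (-2.00, SE 0.060), and in Xlr4c, an X-linked lymphocyte-regulated gene (3.48-fold, -1.80, SE 0.30). In limma the adjusted p of these genes ran from 9.9e-06 for Ccn3 to 0.00968 for Xlr4c. Xlr4c was measured by 1 probe set. Its mean with overexpression, 4.96, lay below 5.07, the lowest overall mean kept, so the size of its fall is uncertain.

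Of the 2102 genes that changed, 812 rose and 1290 fell, and 54 changed at least 2-fold (34 up, 20 down). At an unadjusted p under 0.05 there were 4760. The excess of falls depended on the scaling, since 1019 rose and 964 fell with each array centred on its median, and 1035 rose and 1013 fell after quantile normalization. The other leading rises were the ribonuclease Ang (1.80), Ifi203 (1.77), Ngp (1.66), Ltf (1.65) and Gas6, a ligand of TAM receptors (1.60). The other leading falls were Glrp1 (-1.62), the chemokine Ccl17 (-1.61), Cpne1, a calcium-dependent phospholipid-binding protein (-1.57, or -0.84 with the median of its 9 probe sets, of which 1 fell by 6.80), the zinc transporter Slc39a2 (-1.48), the inflammatory caspase Casp4 (-1.46) and the osteocalcin family gene Bglap2 (-1.41). All passed the limma threshold. On its brightest probe set Ctse changed by only 0.12 (limma adjusted p = 0.453).

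Of the 37 lists, 16 passed camera with overexpression, 9 higher and 7 lower, and 1 of them, the interferon list, passed with an estimated correlation. Of its 62 genes 41 rose and 1 fell (46 and 2 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2.74e-25, adjusted p = 0.00746 with an estimated correlation). After Ifi204 and Ifi203 the largest rise was in Ifit1 (1.29, SE 0.065), and the fall was in Oas1g (-0.58). Monocyte and macrophage genes rose alongside. Of 35 tested 16 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.86e-09, adjusted p = 0.111 with an estimated correlation). Ms4a6c (1.42, SE 0.095), F13a1 (1.39, SE 0.064) and complement C1qb (1.20, SE 0.072) led them. Of 27 secondary granule and mature neutrophil genes 15 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 1.86e-09, adjusted p = 0.156 with an estimated correlation), with the antimicrobial peptide Camp (1.36) next after Ngp and Ltf.

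Mitosis genes had 34 of 59 members higher and 1 lower (45 and 2 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 6.29e-19, adjusted p = 0.0619 with an estimated correlation). The centromere kinesin Cenpe (0.62), survivin Birc5 (0.58) and the transcription factor Foxm1 (0.56) led the rises, and the fall was in Kif20a (-0.54). DNA replication and S phase genes had 9 of 48 higher and 0 lower (14 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 1.78e-06, adjusted p = 0.171 with an estimated correlation), including Msh6 (0.45), Pola1 (0.41) and Prim1 (0.37). Of 17 replication-dependent histones 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.222 with an estimated correlation). H2ac10 and H1f5 rose by 0.72 each and H4c9 fell (-0.70). This list missed the threshold without replicate 2 of the wild type (camera adjusted p = 0.0745) or replicate 1 of the overexpressing cells (camera adjusted p = 0.0599). Of 60 oxidative phosphorylation genes 6 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.000385, adjusted p = 0.0619 with an estimated correlation), with Atp5l (0.39), Ndufa5 (0.38) and Atp5e (0.33) the largest.

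Of 23 mast cell and basophil genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 4.48e-06, adjusted p = 0.0619 with an estimated correlation). The tryptase Tpsb2 (0.72), the carboxypeptidase Cpa3 (0.55) and the basophil protease Mcpt8 (0.53) led them, while the receptor gene Kit fell (-0.36). Of 57 ribosomal protein genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.02, camera adjusted p = 0.0422, adjusted p = 0.156 with an estimated correlation). The largest of these, Rps6 (1.17, SE 0.25), came from 1 probe set, was 0.73 without replicate 1 of the wild type and did not pass without replicate 1 of the overexpressing cells (limma adjusted p = 0.106), and Rpl17 (0.54) and Rpl32 (0.43) followed. This list missed the threshold in 11 of 19 alternative settings, among them leaving out the first wild-type array (camera adjusted p = 0.0796) or either overexpression array (camera adjusted p = 0.0686 and 0.0512). Of 26 B lymphoid genes 7 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 0.000109, adjusted p = 0.0619 with an estimated correlation), led by the transcription factors Spib (-0.78) and Irf4 (-0.69) and by Ms4a1 (-0.68). On the brightest probe sets the B lymphoid median was -0.037 and the list did not pass (camera adjusted p = 0.465).

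Of 29 immediate-early and stress genes 11 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 2.99e-06, adjusted p = 0.0619 with an estimated correlation). Egr1 (-0.85), Atf3 (-0.48) and Btg2 (-0.47) led them. With the median of its probe sets on each array Egr1 did not pass (-0.29, limma adjusted p = 0.484), although all 5 of its probe sets were lower, with a median change of -1.01. Of 32 genes of the unfolded protein response 11 fell and 0 rose (17 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 1.43e-05, adjusted p = 0.167 with an estimated correlation), led by the cystine transporter Slc7a11 (-0.71) and Chac1 (-0.48). With the median of their probe sets on each array Slc7a11 (-0.46, limma adjusted p = 0.138) and Chac1 (-0.05, limma adjusted p = 0.817) did not pass. Singly, all 16 probe sets of Slc7a11 were lower (median change -0.69), and for Chac1 4 were lower and 2 higher (median change -0.435). Heme and iron handling genes had 10 of 18 lower and 1 higher (12 and 2 adjusted over the list alone, median -0.30, camera adjusted p = 0.00139, adjusted p = 0.0992 with an estimated correlation). The iron exporter Slc40a1 fell (-0.86) and the transferrin receptor Tfrc rose (0.56). Of 32 p53 targets 8 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.271 with an estimated correlation), with Plk2 (-0.68), Btg2 and Psrc1 (-0.43) the largest. The p53 list missed the threshold with the dimmest 50% of genes left out (camera adjusted p = 0.0544), with the median of probe sets (camera adjusted p = 0.131) and on the brightest (camera adjusted p = 0.0766).

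By camera with the preset correlation, lists of histone demethylases and of COMPASS and Trithorax subunits fell slightly. Other Polycomb subunits (camera adjusted p = 0.541) and the KDM2B partners (camera adjusted p = 0.749) did not pass. Histone demethylases other than Kdm2b had 4 of 18 lower and 0 higher (6 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.013, adjusted p = 0.167 with an estimated correlation). Kdm3b (-0.83, SE 0.060) fell most, followed by Kdm4b (-0.33) and Kdm3a (-0.29). The calls of Kdm3a and Kdm4b ended in 12 and 6 of 17 alternative settings, Kdm3a's without any array of the overexpression cohort, while Kdm3b kept its call in all 17. Of 15 COMPASS and Trithorax subunits 3 fell and 0 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.00892, adjusted p = 0.167 with an estimated correlation). They were Kmt2a (-0.43), Men1 (-0.30) and Ash1l (-0.29), and on their brightest probe sets Men1 and Ash1l changed by 0.01 and 0.04. After quantile normalization both lists missed the camera threshold (adjusted p = 0.0835 for the demethylases and 0.0517 for COMPASS). The demethylase list also missed it with the dimmest 50% of genes left out (camera adjusted p = 0.0538), and the COMPASS list on the brightest probe sets (median -0.02, camera adjusted p = 0.538). Kdm3b and Egr1 lie close together on the chromosome, and neighbouring genes fell with them, including Brd8 (-0.99), Cdc23 (-0.99), Kif20a (-0.54), Fam53c (-0.87), Etf1 (-0.66) and Hspa9 (-0.66).

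**Figure D3:**
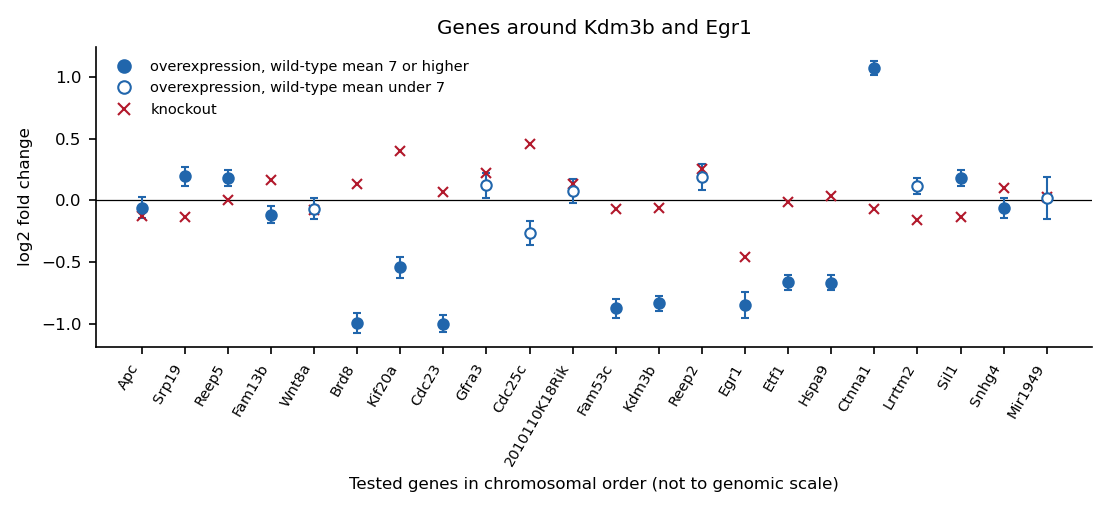
Log2 fold changes of tested genes around Kdm3b and Egr1 in chromosomal order, for overexpression (blue circles, with bars of 1 SE; open for genes whose wild-type mean was under 7) and for the knockout (red crosses). The bright genes from Brd8 to Hspa9 lay between -0.99 and -0.54 with overexpression, and the neighbouring Ctnna1 at 1.07.

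Lists that did not pass camera with overexpression had medians from -0.23 to 0.24 and adjusted p of 0.0569 or higher. They were CDK inhibitors, cholesterol synthesis, cytokine receptors, dendritic cells and MHC class II, eosinophils, erythroid genes, glycolysis and hypoxia, the Hoxa cluster, inflammation and NF-kB, megakaryocytes, primary neutrophil granules, natural killer genes, the Notch pathway, other Polycomb subunits, the KDM2B partners of its Polycomb complex, RAS-ERK output, ribosome biogenesis and MYC, the Y-linked genes, stem and progenitor genes, stroma and T lymphoid genes. Medians, means and camera directions differed in sign for CDK inhibitors, cytokine receptors, eosinophils, the KDM2B partners, and erythroid, stem and T lymphoid genes. Among the KDM2B partners Pcgf1 fell (-0.64).

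Leaving out an array of the overexpression cohort gave 540 to 1082 changed genes (576 and 540 without either wild-type array, 997 and 1082 without either overexpression array). The count was 1354 without the filter on dim genes, 528 with the median of a gene's probe sets, 1176 on the brightest probe set, 3238 with a trended and robust variance and 1005 from the cohort's 4 arrays alone. The limma calls of 20 named genes ended with at least 1 array left out, with adjusted p from 0.0509 to 0.169. They were Ash1l, Atp5e, Atp5l, Btg2, Chac1, Foxm1, Kdm3a, Kdm4b, Kmt2a, Men1, Ms4a1, Msh6, Ndufa5, Pola1, Prim1, Psrc1, Rpl17, Rpl32, Rps6 and Xlr4c. With the median or the brightest of a gene's probe sets, all of these except Ms4a1 and Xlr4c lost their calls, as did Atf3, Birc5, Cpa3, Ctse, Egr1, Mcpt8 and Slc7a11. The filter on dim genes left Ms4a1 untested on its brightest probe set, and Xlr4c has 1 probe set. Neither is therefore shown to withstand the choice between the median and the brightest probe set.

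The direct test of the difference asked which genes responded differently to loss and to gain of Kdm2b. Interferon-stimulated and mast cell lists differed between the comparisons, with lower changes in the knockout. The mast cell list's rise with overexpression passed camera with the preset correlation and not with an estimated one. It also missed the threshold on the brightest probe sets (median 0.098, camera adjusted p = 0.0712). The change in the knockout exceeded that with overexpression most in Stfa2l1 (difference 2.83, SE 0.12), Bglap2 (2.53, SE 0.16), Csta3 (2.51, SE 0.15) and Ccl17 (2.41, SE 0.093). It lay furthest below in Ly6g (-3.07, SE 0.14), F13a1 (-2.82, SE 0.090), Ifi204 (-2.62, SE 0.16) and Ms4a6b (-2.38, SE 0.11). All 8 had a limma adjusted p of 9.93e-05 or lower. Some started from unlike levels in the wild types of the knockout and the overexpression cohort. These were Stfa2l1 (6.62 against 11.1 and 11.2), Bglap2 (5.09 against 9.25) and Csta3 (4.72 against 9.15 and 9.29). The Csta3 value of 4.72 lay below 5.07, the lowest overall mean kept. Ccl17 (9.55 and 10.5) and F13a1 (8.23 and 7.93) lay closer. Whether the starting level shaped these differences was not tested.

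In limma 1875 genes differed between the comparisons, 1112 with the higher change in the knockout and 763 with the lower. With each array centred the split was 866 to 921, and after quantile normalization 928 to 872. Of 62 interferon-stimulated genes 51 differed toward lower in the knockout and 1, Ifi44, toward higher (56 and 1 adjusted over the list alone), with a median difference of -0.85 (camera adjusted p = 5.71e-41, adjusted p = 0.00286 with an estimated correlation). In 35 of them the fall in the knockout and the rise with overexpression each passed the threshold, as for Ifit1 (-0.68 and 1.29), Irf7 (-0.49 and 0.97), Rsad2 (-0.66 and 0.81) and Isg15 (-0.22 and 0.82). The cohorts, treated as normalized separately, lay far apart for Ifit1. Its arrays read 10.9 in the knockout cohort's wild type and 10.2 in the knockout. They read 7.67 and 7.57 in the other wild type and 8.87 and 8.94 with overexpression. Overexpressing cells thus stayed below knockout cells for Ifit1. Whether the starting level shaped such opposite changes was not tested. Of 23 mast cell and basophil genes 13 differed toward lower in the knockout and 1 toward higher (15 and 1 adjusted over the list alone, median difference -0.60, camera adjusted p = 4.89e-12, adjusted p = 0.0406 with an estimated correlation). In 7 of them both changes passed, including Tpsb2 (-1.24 and 0.72), Mcpt8 (-0.70 and 0.53) and Cpa3 (-0.37 and 0.55).

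**Figure D4:**
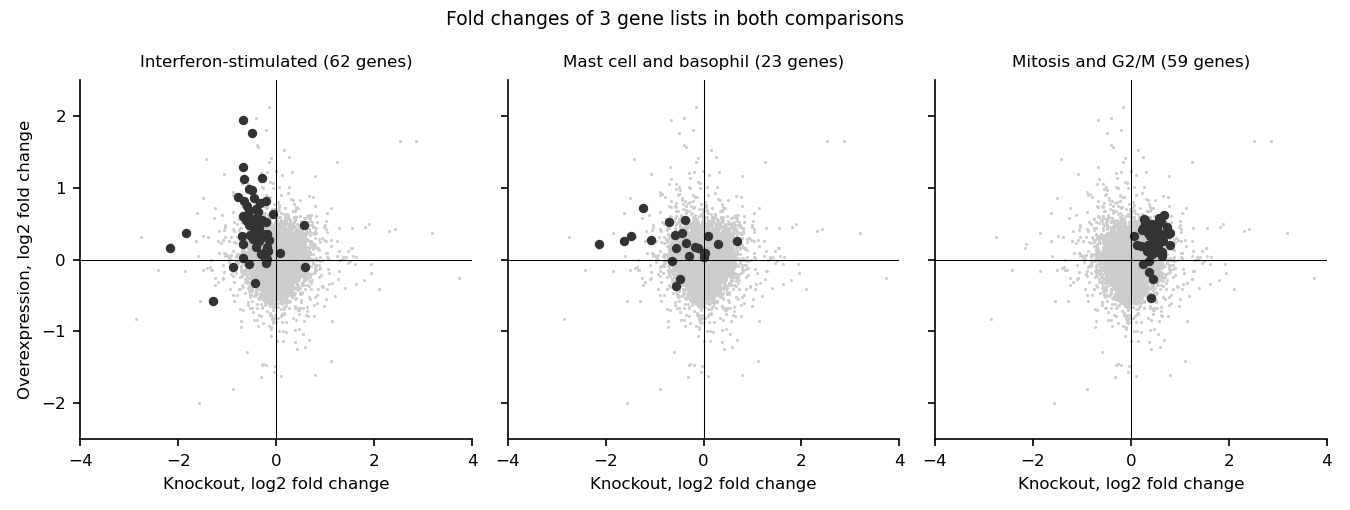
Log2 fold change in the knockout (horizontal) against that with overexpression (vertical) for 62 interferon-stimulated, 23 mast cell and basophil and 59 mitosis genes (black), over all 16171 tested genes (grey). In the interferon list 35 genes fell in the knockout and rose with overexpression, and in the mitosis list 30 genes rose in both.

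The remaining lists whose changes differed did so with the preset correlation and not with an estimated correlation. Monocyte and macrophage genes had 16 of 35 lower in the knockout by comparison and 1 higher (18 and 2 adjusted over the list alone, camera adjusted p = 1.43e-11, adjusted p = 0.154 with an estimated correlation). Natural killer genes had 5 of 14 lower and 2 higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.0045, adjusted p = 0.177 with an estimated correlation). On the other side lay ribosome biogenesis and MYC (11 of 55 higher, 1 lower, 22 and 1 adjusted over the list alone, camera adjusted p = 1.54e-06, adjusted p = 0.251 with an estimated correlation) and immediate-early genes (9 of 29 higher, 0 lower, 10 and 0 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.126 with an estimated correlation). Mitosis genes (8 of 59 higher, 0 lower, 14 and 1 adjusted over the list alone, camera adjusted p = 0.000645, adjusted p = 0.38 with an estimated correlation) rose in both cohorts and by this test further in the knockout. The unfolded protein response (7 of 32 higher, 1 lower, 9 and 1 adjusted over the list alone, camera adjusted p = 0.00504, adjusted p = 0.38 with an estimated correlation), primary granules (4 of 15 higher, 1 lower, 8 and 1 adjusted over the list alone, camera adjusted p = 0.00556, adjusted p = 0.365 with an estimated correlation) and heme and iron handling (8 of 18 higher, 1 lower, 10 and 1 adjusted over the list alone, camera adjusted p = 0.00939, adjusted p = 0.191 with an estimated correlation) completed them. Lists not named here did not pass this test.

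Across all genes the changes were nearly unrelated. Pearson's r between the knockout and overexpression fold changes was 0.0046 and Spearman's rho 0.0051 over 16171 genes, which are not independent replicates. Called genes overlapped in every combination of directions. The fit gives both comparisons the same spread for each gene, so genes with little spread can be called in both. Independent lists are therefore only a rough reference. There were 530 genes called in both comparisons against 241.9 for independent lists. Of these 161 rose in both (49.7 for independent lists), among them Ngp, Ltf and 30 mitosis genes, and 105 fell in both (69.6), including Ccn3 and Ms4a1. Another 143 fell in the knockout and rose with overexpression (43.8), such as F13a1, and 121 did the reverse (78.9), such as Ccl17. The overlap was 201 to 338 genes with any array left out.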

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

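The list test of the difference between the comparisons and all tests of explanations in this part were chosen only after the results were seen.

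Interferon-stimulated genes and mast cell and basophil genes stood out because their changes differed between loss and gain of Kdm2b in a test of the difference itself. The knockout change minus the overexpression change had a median of -0.85 over 62 interferon-stimulated genes (camera adjusted p = 0.00286 with an estimated correlation) and of -0.595 over 23 mast cell and basophil genes (camera adjusted p = 0.0406 with an estimated correlation). In the interferon list 51 genes differed toward lower in the knockout and 35 passed the threshold in opposite directions in the 2 comparisons, as did 7 mast cell and basophil genes. Some of these genes, such as Ifit1 and Tpsb2, started from unlike levels in the wild types, and the effect of this was not tested. The rise of the mast cell list with overexpression did not pass with an estimated correlation (camera adjusted p = 0.0619) or on the brightest probe sets (camera adjusted p = 0.0712), and its result is given as a value only.

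For the interferon list, a fall confined to members on the chromosome of Kdm2b was argued against in the knockout. Those 10 members had a median of -0.582. Without them the median was -0.42, with 36 of the 52 left lower (camera adjusted p = 0.00824 with an estimated correlation), and falls lay on 15 other chromosomes. Genes carried along with the Kdm2b locus that act on genes elsewhere were not tested and stay open. An even loss of monocytes and macrophages in the knockout was argued against too, because as a list their markers fell less. Their median was higher than that of the interferon list by 0.311 (95% bootstrap interval over genes, which are not replicates, 0.156 to 0.411). A loss of some of these cells stays open. Of the 35 markers 12 fell and 1 rose, with F13a1 at -1.43, C1qa at -0.88 and Cx3cr1 at 1.12. With overexpression the same comparison of list medians gave -0.183 (-0.394 to 0.0239), an interval that includes 0. A higher share of monocytes and macrophages there cannot be told apart from a rise within the cells. Another exposure of one animal or culture, such as an infection, cannot be told apart either, since each group carries 1 title code, and an effect of KDM2B on interferon signalling therefore remains a hypothesis.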

How the results depend on the processing

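All alternatives for genes, lists and Kdm2b were planned, and none was added later. The planned comparison of the wild-type groups was not run, because shared repeated values led the cohorts to be treated as normalized separately, and the fit to 4 arrays gave no value for the difference between comparisons. The Kdm2b change kept its direction and its side of the threshold in every alternative run, with -1.17 to -0.98 in the knockout and 1.09 to 1.28 with overexpression when single arrays were left out. The interferon list kept its calls in all 19 settings in both comparisons, and the mitosis and mast cell lists kept theirs in the knockout. The mast cell median there was -0.15 on the brightest probe sets against -0.44 as reported, while over all settings the interferon median in the knockout stayed between -0.46 and -0.36 and the mitosis median between 0.45 and 0.56.

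Counts of genes moved more. Without the filter on dim genes, overexpression called 1354 genes and both comparisons shared 307 calls. With the median of a gene's probe sets the knockout called 545 genes, overexpression 528 and the difference 526, with 97 shared and a correlation of 0.019 between the fold changes. On the brightest probe set these were 405, 1176, 661, 115 and -0.028. A trended and robust variance gave 3238 genes with overexpression, 2892 for the difference and 986 shared. Fitting only the 4 arrays of the comparison gave 1005 with overexpression and 275 shared. Tested singly, 376 probe sets passed in the knockout and 916 with overexpression. With an estimated correlation 3 lists passed in the knockout and 1 with overexpression, while fry in its mixed form called all 37 lists in each comparison. Beyond the change in degrees of freedom described above for the estimated correlation, the cause of each of these changes was not tested.

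Leaving out single arrays gave 840 to 1856 genes in the knockout, 540 to 1602 with overexpression, 957 to 1526 for the difference, 201 to 338 shared calls and correlations from -0.0051 to 0.0138. Counts for the difference were 966, 1030, 982 and 1113 without a knockout-cohort array and 1030 and 957 without an overexpression-cohort wild-type array. The lowest counts came from leaving an arm with 1 array, which is then assumed to vary like the other groups. Of the named genes, 75 results over single arrays left out fell below the threshold and 805 did not, and 33 did so with the median of the probe sets and 27 on the brightest probe set. Reversals occurred only on the brightest probe set, for Srr in the knockout (-0.274) and for Men1 (0.0129) and Ash1l (0.0434) with overexpression, none of them past the threshold there.

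The replicate numbers only name arrays, since the correlations of replicate differences between groups lay between -0.067 and 0.060. With the replicate number as a block (replicate block) 1630 genes passed in the knockout, 1704 with overexpression, 1573 for the difference and 430 in both. It ended the calls of Ndufa5 and of the ribosomal protein list with overexpression and no other call of a named gene or list. Signal over background limits dim probe sets, and genes whose mean lay below 5.07 were not tested.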

Other observations

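The genes in the first paragraphs and all tests of explanations in this part were chosen only after the results were seen. The gene lists and the design behind the other tests here had been fixed before the data were examined.

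With overexpression, single genes known from tissue macrophages rose in limma. They included the scavenger receptor Cd163 (1.08, SE 0.10), the folate receptor Folr2 (1.01, SE 0.059), selenoprotein P Selenop (0.87, SE 0.087) and the lipid carrier Fabp4 (1.23, SE 0.096), beside the acute phase gene Saa3 (1.57, SE 0.086). Of these Cd163 belongs to the fixed monocyte and macrophage list, which passed with the preset correlation (camera adjusted p = 1.86e-09) and not with an estimated correlation (adjusted p = 0.111). Among single genes that fell were Alox15 at -1.22 (SE 0.080), Mgl2 at -0.97 (SE 0.059), Itgax at -0.88 (SE 0.090) and Dcstamp at -1.01 (SE 0.062), while the fixed list of dendritic cells and MHC class II did not pass (camera adjusted p = 0.0642). In the knockout Ccl17 (0.79), Alox15 (0.59), Cd209a (0.77) and Retnla (1.19) rose, and the changes of these 4 genes differed between the comparisons, with limma adjusted p from 2e-05 for Ccl17 to 0.0091 for Cd209a. The dendritic cell list did not pass in the knockout either (9 of 28 higher, 6 lower, camera adjusted p = 0.275), where its members Ccr7 (-0.81), Fscn1 (-0.72), Cd83 (-0.65) and Ccl22 (-0.46) fell.

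In the knockout, the cadherin Cdh17 (1.53, SE 0.074), the integrin Itgae (1.46, SE 0.093), Ptk7 (1.37, SE 0.081), the claudin Cldn1 (1.14, SE 0.065), Cd7 (1.79, SE 0.060) and Cd34 (0.88, SE 0.087) rose past the limma threshold. These are single genes, and the fixed list of stem and progenitor genes did not pass in the knockout (median -0.06, camera adjusted p = 0.404). None of Cdh17, Itgae, Ptk7 and Cd34 passed with overexpression, Cd7 and Cldn1 fell there, and all 6 changes differed between the comparisons with limma adjusted p of 0.0081 or lower. Ccn3 fell in both comparisons (-1.57 in the knockout, -2.00 with overexpression).

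With overexpression 8 of the 12 tested genes from Brd8 to Hspa9 fell, with a median of -0.838 that leaves 56% of the wild-type level, while the dimmer Gfra3 (0.12), Cdc25c (-0.26), 2010110K18Rik (0.07) and Reep2 (0.19) between them did not pass. Unrelated genes lying side by side by chance were argued against, as 0 of 10000 shuffles of the fold changes over the gene order held a stretch with 8 such falls and the most in any shuffle was 5. The length of the stretch and the limit of 0.5 for a fall were chosen after the falls were seen. Falls on only a few probe sets, as from sequence variants, were argued against, since 96.3% of the 108 bright probe sets of these genes (104) were lower, with a median of -0.802. These genes were picked for lower means, which raises that share. One copy of the segment missing in the overexpressing cells stays open, because the stretch was picked for its falls, so that the least fallen bright gene inside it, Kif20a at -0.541, decides nothing. The neighbouring Ctnna1 was higher on all 17 of its probe sets (1.07), and neither copy number nor a link to Kdm2b was tested.

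The Y-linked genes Uty, Eif2s3y and Kdm5d fell in the knockout to 53.9%, 61.5% and 62.3% of wild type, while their X-linked homologs did not pass the threshold. Falls on only a few probe sets, as from sequence variants, were argued against, because 97.2% of 36 bright probe sets (35) were lower. The means of these genes were already known to be lower, which raises that share. A share of knockout cells without a Y chromosome stays open. The 3 falls differed by at most 1.57 standard errors, but these treat the genes as independent. Their estimated correlation was 0.735, so the comparison decides nothing. Kdm5d did not pass with the median of its probe sets (limma adjusted p = 0.0864), nor Eif2s3y on its brightest (limma adjusted p = 0.097) or without replicate 1 of the wild type (limma adjusted p = 0.0515). With overexpression the changes of the Y-linked genes differed by 5.74 standard errors computed in the same way, and of the 3 Kdm5d alone fell (-0.70). Among the X-linked homologs Eif2s3x fell there (-0.357, limma adjusted p = 0.00921), while Kdm6a and Kdm5c did not pass. No biological explanation through Kdm2b was tested.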
